A study of Homo sapiens with 2 samples.

How the data were processed

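Gene expression was measured in Huh7 cells, an established human hepatocellular carcinoma line, transfected with Lipofectamine and either a control siRNA or an siRNA against TYRO3. Total RNA was labelled with biotin and hybridised to an Affymetrix GeneChip, 1 array per group and 2 arrays in all, per the labels' protocols. The deposited table holds log2 signals for 54675 probe sets. The authors made these values with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes. RMA corrects the background and summarises the probes of each probe set on the log2 scale, and as a rule also brings arrays to a common distribution. The settings used were not given in the sources used here. The deposited log2 values ran from 1.99 to 14.6 on the control array and from 2.06 to 14.6 on the TYRO3 siRNA array. Their medians were 5.91 on the control array and 5.97 on the TYRO3 siRNA array, and 2163 probe sets had the same value on both. The summarised columns as deposited thus do not share one distribution. From summarised values it cannot be told whether the probe signals were brought to one distribution beforehand. The medians of the columns differ by 0.06, as much as some of the smaller list medians. The percentiles of lists do not move with such a constant shift. Summarising over only 2 arrays leaves no estimate of the spread between cultures, and scanner intensities and detection calls were not used here.

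Probe sets were paired with genes through a platform annotation table. After 62 manufacturer's control probe sets were set aside, 41091 probe sets named 1 gene, 1801 named several genes and 11721 were not named in that table. Gene identifiers were used to update the symbols of 41037 single-gene probe sets to those of the RefSeq annotation of GRCh38.p14, and the other 54 kept the symbol of the table. No genome build was given for the array, so no coordinates are printed. Only single-gene probe sets entered gene values. A gene was represented by its probe set with the highest mean over both arrays, which gave 19777 genes. A level filter kept the 11867 genes whose mean log2 signal was at or above the 40th percentile of all genes, a log2 signal of 6.26. Differences are given as TYRO3 siRNA minus control siRNA on the log2 scale, and folds are 2 raised to that difference. The filter is on the mean of both arrays and is not a test against background, so a difference rests on a dim signal where a probe set was under it on either array.

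With 1 array per group no p-value across arrays was computed. The one error these arrays give is technical: the pooled SD of the log2 difference between probe sets of the same gene, over 5540 genes with 2 or more probe sets above the filter. It leaves out the spread between cultures and transfections. Genes were counted past a fixed size of 2-fold, and 63 gene lists were fixed before the data were examined. Of their 1252 entries, 1112 had a single-gene probe set and 925 passed the level filter. For the 58 lists with at least 5 genes above the filter, the median log2 difference was placed among the medians of 10000 random gene lists of the same size, drawn from 20 bins of mean signal. A list outside the central 95% (below percentile 2.5 or above 97.5) is described as standing apart. By construction about 2.9 of 58 lists would do so, and genes that are regulated together can exceed that without any effect of the siRNA. The percentile therefore describes these 2 arrays and is not a test between conditions.

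The genes named were chosen by a rule set before the data were examined. They are TYRO3, AXL, MERTK, GAS6 and PROS1, and the 15 largest positive and 15 largest negative differences above the filter, leaving out genes whose probe sets above the filter disagreed in sign. They also include the 2 highest and 2 lowest members of each list described. Lists described in detail are those outside the central 95% and a set chosen beforehand. Alternatives were the mean or median over a gene's probe sets, scaling to the 12 of 15 housekeeping genes that had a single-gene probe set, removal of the level-dependent trend by lowess (fraction 0.2), other level filters, other sizes, list means and unmatched random lists. Random lists matched on level and on the genomic span of the gene were added after the data were seen. The matching of list symbols to probe sets was corrected after list percentiles had first been seen, which left the number of lists standing apart as it was. On simulated data with a spread of 0.21 on the log2 scale, 98.5% of 200 genes changed by 1.5 on the log2 scale passed the 2-fold size, among 11867 genes, and no unchanged gene did (0 calls). This outcome follows from the spread that was set, which leaves out the spread between cultures. The observed differences had an SD of 0.32, so the simulation does not show how reliable the 2-fold counts are. Over 4000 simulated lists of 15 genes, 5.35% of unshifted lists fell outside the central 95%, and 85.6% of lists shifted by 0.25 lay above it, with 500 random lists behind each percentile. The differences were shuffled between genes for this, which removes joint regulation. The shift of 0.25 is also larger in size than the median of any list that stood apart. The number of simulated lists was raised because a first run with far fewer had placed a larger share of unshifted lists outside. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.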

Results

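The data compare the transcriptome of Huh7 hepatocellular carcinoma cells with and without knockdown of TYRO3, a receptor tyrosine kinase of the TAM family (TYRO3, AXL and MERTK), by siRNA. There was 1 array of control siRNA cells and 1 array of TYRO3 siRNA cells. No value below therefore has a replicate error, and differences are differences between these 2 arrays. The technical yardstick was the pooled SD of the log2 difference between probe sets of the same gene, which was 0.21. Among 3212 genes with exactly 2 probe sets above the level filter, the log2 differences of the 2 probe sets correlated with a Pearson r of 0.59 across genes, which are not independent replicates. The 18 hybridisation spike-in probe sets, added at a set amount to each array, read a median of 0.11 higher on the TYRO3 siRNA array, with a range from -0.09 to 0.36. RNA integrity was alike by the 3′ to 5′ control probe sets. The 3′ minus 5′ log2 signal was 0.01 on the control array and 0.02 on the TYRO3 siRNA array for GAPDH, and 0.74 and 0.66 for ACTB.

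TYRO3 itself was lower on the TYRO3 siRNA array on both of its probe sets. The brighter one went from a log2 signal of 8.95 to 7.15, a difference of -1.80, or 28.8% of control. The dimmer one went from 7.85 to 7.06, a difference of -0.79, or 58.0% of control. Both differences exceeded the spread between probe sets of one gene, and their sizes differed from each other. The probe set of the sequence-related TYRO3P pseudogene, looked up after the values were seen, was below the level filter, with log2 signals of 5.11 on the control array and 5.38 on the TYRO3 siRNA array. The other TAM receptors and the ligands differed less than either TYRO3 probe set. MERTK, the TAM receptor best known from clearance of dying cells, differed by -0.10 and 0.05 on its 2 probe sets above the filter. AXL was below the level filter on both probe sets, with log2 signals of 5.98 on the control array and 6.44 on the TYRO3 siRNA array for the brighter one. That is a difference of 0.46, while the dimmer one had the same value on both arrays. GAS6, a ligand of all TAM receptors, differed by 0.13, and PROS1, the anticoagulant protein S and a TAM ligand, by -0.43 on its single probe set. The PROS1 difference is beyond the technical spread of 0.21, which leaves out the spread between cultures. Differences of all genes above the filter had an SD of 0.32, so a value of this size does not single PROS1 out.

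**Figure D1:**
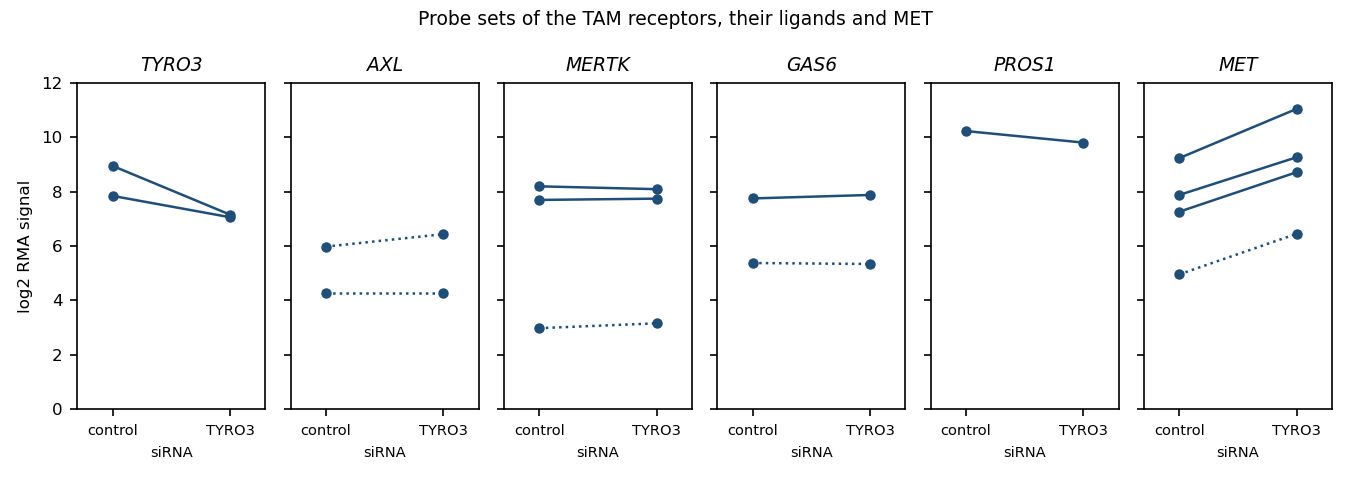
Log2 RMA signal (vertical axis) on the control siRNA and TYRO3 siRNA arrays (horizontal axis) for every single-gene probe set of TYRO3, AXL, MERTK, GAS6, PROS1 and MET. Each line is 1 probe set, dotted where its mean is below the level filter of 6.26; both TYRO3 lines go down, by 1.80 and 0.79, and all 4 MET lines go up.

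Across the transcriptome most genes differed little. Of 11867 genes above the level filter, 11099 (93.5%) lay within 1.5-fold on the 2 arrays, whose signals correlated across genes with a Pearson r of 0.99. At least 2-fold differences were found for 52 genes that were higher and 67 that were lower with TYRO3 siRNA. With the housekeeping genes set equal the split was 67 higher and 46 lower, so the balance between the directions depends on the scaling. In the values as deposited, 30 of the 52 higher and 27 of the 67 lower genes rest on 1 probe set above the filter. Another 9 of the 2-fold genes had probe sets above the filter that disagreed in sign, and these genes stay in the counts. Requiring every probe set of a gene with 2 or more to pass 2-fold left 2 higher and 4 lower genes.

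On the brightest probe set of each gene, the largest positive difference was that of PTPMT1, a phosphatase of mitochondrial cardiolipin synthesis, which was 5.26-fold higher on its brighter probe set and 2.77-fold higher on the other. MET, the receptor of hepatocyte growth factor, was 3.52-fold higher, from a log2 signal of 9.24 to 11.05. Of its other 3 probe sets, 2 were 2.62- and 2.74-fold higher, and 1 below the level filter went from a log2 signal of 4.96 to 6.45. CYP24A1, which inactivates vitamin D, was 4.68-fold higher on its single probe set. TUBA1A, an alpha-tubulin with near-identical copies in the genome, went from a log2 signal of 6.25, just under the level filter, to 8.59 on its single probe set, a difference of 2.34. Its relatives TUBA1B and TUBA1C, looked up after the values were seen, differed by 0.01 and 0.05 on the log2 scale. PDCD6, a calcium-binding protein, was 3.39-fold higher and MAOB, a monoamine oxidase, 3.09-fold higher, each on 1 probe set above the filter, while their dimmer probe sets did not show it. PPL (periplakin, a cell junction protein) also started under the filter, at a log2 signal of 6.23, and was at 7.66 with TYRO3 siRNA. The keratin KRT23 was 2.84-fold higher, CEMIP, which takes part in hyaluronan breakdown, 2.57-fold, and LGALS1 (galectin-1) 2.43-fold. CEMIP's second probe set differed by only 0.10 on the log2 scale. ERCC5, an endonuclease of nucleotide excision repair, was 2.81-fold higher, and DNMT3B, a de novo DNA methyltransferase, 2.60-fold. PIP4K2A, a phosphoinositide kinase, was 2.79-fold higher, with its 3 probe sets between 0.63 and 1.48 on the log2 scale. GPCPD1, a glycerophosphocholine phosphodiesterase, was 2.53-fold higher and MFSD6 2.66-fold. With the mean over all probe sets, 4 of these genes were under 2-fold: PIP4K2A at 0.99, CEMIP at 0.73, PDCD6 at 0.56 and MAOB at 0.54.

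On the same basis the largest negative difference was that of NDUFB7, a subunit of respiratory complex I, at 18.5% of control on its bright probe set. Its other probe set, below the level filter, differed by only -0.25 on the log2 scale, and the mean of both was -1.34, a smaller difference than that of KLHL15. SLC40A1, the iron exporter ferroportin, was at 25.2% of control, also on 1 probe set above the filter. Its other probe set, below the filter, differed by -0.21 on the log2 scale, and the mean of both was -1.10. KLHL15, an adaptor of a ubiquitin ligase, was at 31.4%, and MYO5A, a myosin motor, at 32.7%. The MYO5A probe sets above the filter differed by -1.61 and -0.51 on the log2 scale, and those below it by -0.28 and -0.13. YOD1, a deubiquitinase, was lower on both probe sets, by log2 differences of -1.52 and -1.46, the second ending under the level filter at a log2 signal of 5.76. TGFBR1, the type I receptor of TGF-beta, was at 35.7% of control, and FRK, a Src-related kinase, at 36.4%. Their second probe sets above the filter differed by -0.61 and -0.36. RBP2, a cellular retinol-binding protein, was at 36.8%, NAPEPLD, a phospholipase, at 37.4%, and TOB2, an antiproliferative protein, at 37.6%. FAM3C, a secreted protein, was at 37.8%, CREBRF at 38.7%, the heme-binding plasma protein HPX at 39.0%, and the cap methyltransferase CMTR2 at 39.3%. All 4 CREBRF probe sets above the filter were lower, between -1.37 and -0.56, and both HPX probe sets were lower, by -1.36 and -0.99. With the mean over all probe sets, 7 of these genes were under 2-fold: FRK at -0.91, TGFBR1 at -0.80, TOB2 and CREBRF at -0.79, NAPEPLD at -0.72, MYO5A at -0.63 and FAM3C at -0.60.

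**Figure D2:**
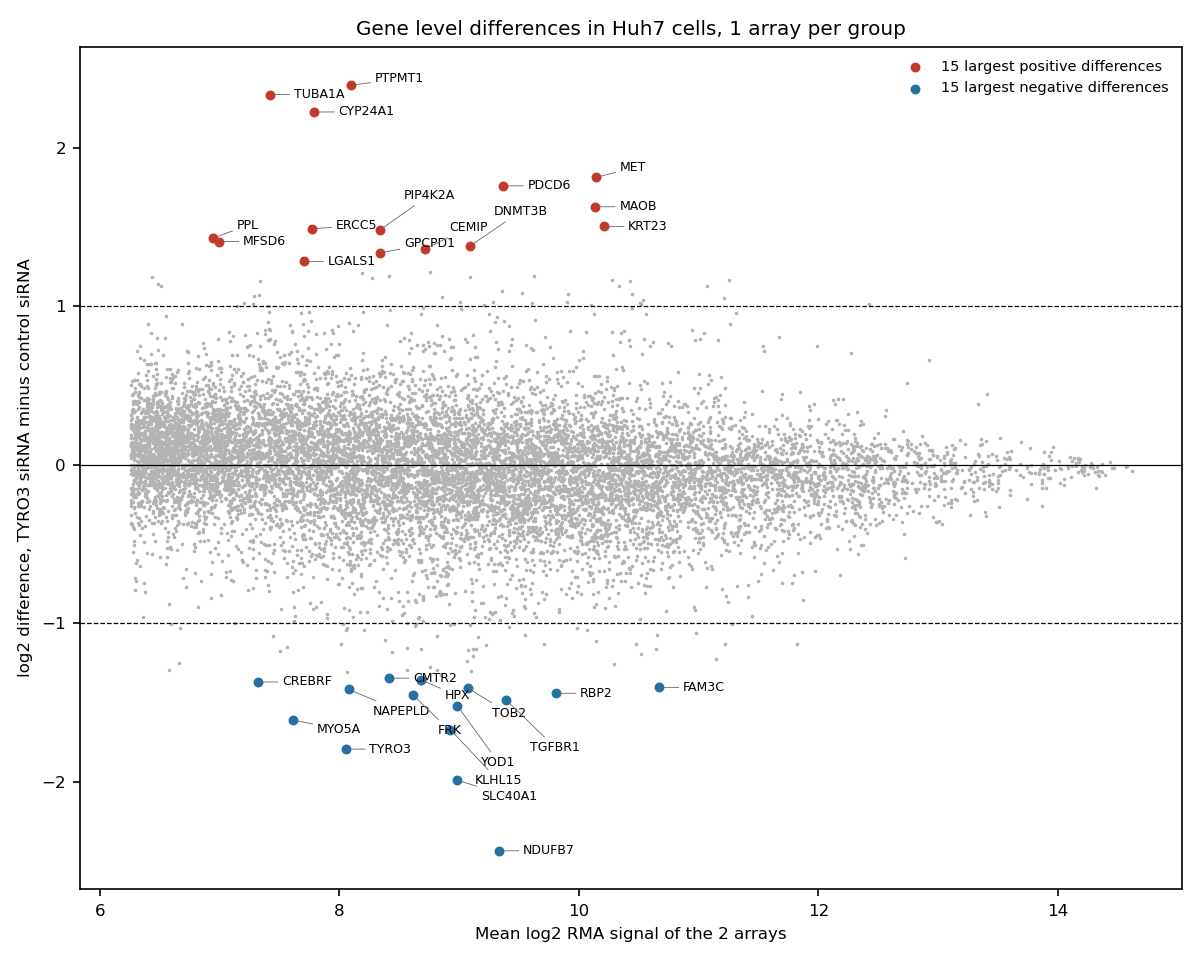
Log2 difference, TYRO3 siRNA minus control siRNA (vertical axis), against the mean log2 RMA signal of the 2 arrays (horizontal axis) for the 11867 genes above the level filter, 1 point per gene. The 15 largest positive and 15 largest negative differences are named, and dashed lines mark 2-fold; NDUFB7, at -2.44, lies lowest and PTPMT1, at 2.40, highest.

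Proliferation genes were slightly lower as a group. In the mitosis list 27 of 30 genes were lower and 3 higher, with a median log2 difference of -0.20 at percentile 0.65 of random lists matched on signal. KIF23, a kinesin of cytokinesis, was 2.01-fold lower and KIF11, a spindle kinesin, 1.45-fold lower, while MKI67 and CENPF differed by 0.19 and 0.09. In the DNA replication list 21 of 28 genes were lower, with a median of -0.17 at percentile 1.52. CCNE2 (cyclin E2) was 2.42-fold lower and the DNA methylation cofactor UHRF1 differed by -0.48 on the log2 scale, whereas E2F1 and RFC4 were both 1.25-fold higher. Only KIF23 and CCNE2 passed 1.5-fold in these 2 lists, and the other members differed by less. Random lists matched on signal were themselves centred at -0.07 for mitosis and -0.06 for DNA replication. Scaled to housekeeping genes, the list medians were smaller, at -0.11 for mitosis and -0.08 for DNA replication. With the level trend removed they were -0.12 and -0.09. The DNA replication list was no longer outside when its mean was used, at percentile 9.62.

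Epithelial genes as a list were higher, with a median log2 difference of 0.19 at percentile 99.9. Of 15 genes above the filter 11 were higher and 4 lower. The tight junction protein CLDN1 was 2.19-fold higher and the keratin KRT19 2.04-fold higher, but the adherens junction protein CDH1 (E-cadherin) was 1.54-fold lower and TJP1 (ZO-1) differed by -0.37 on the log2 scale. KRT19 is also a bile duct marker, and the cholangiocyte marker list as a whole had a median of 0.00 at percentile 52.2. The mesenchymal list did not stand apart. It had 5 of 10 genes higher and 5 lower, and a median of -0.00 at percentile 37.1, with a median of 0.08 when the housekeeping genes were set equal and a list mean of 0.12. Its members VIM and S100A4 were 1.64- and 1.53-fold higher, and THY1 and ZEB1 1.28- and 1.27-fold lower.

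Inflammatory NF-kB genes were higher, with 12 of 14 genes above 0 and a median of 0.18 at percentile 98.9. The chemokine CXCL3 went from a log2 signal of 5.95, under the level filter, to 7.08, and CXCL2 was 1.76-fold higher. SOD2, the mitochondrial superoxide dismutase, was 1.32-fold lower and the inhibitor NFKBIA differed by -0.11. Interferon-stimulated genes, which respond to foreign RNA, did not stand apart, with a median of -0.10 at percentile 6.46. In that list IFIT1 and IFIT5 were 1.55- and 1.49-fold lower and OAS1 and MX2 differed by 0.44 and 0.28 on the log2 scale. The median of the interferon list turned to 0.01 when a gene's probe sets were averaged and to 0.08 with the stricter level filter, and the list lay outside, at percentile 2.24, once the level trend was removed. The p53 target list had 12 of 17 genes higher and a median of 0.17 at percentile 97.8. GDF15, a stress-induced cytokine, was 2.24-fold higher and TP53INP1 1.57-fold, while RRM2B, a ribonucleotide reductase subunit, was 1.61-fold lower and the death receptor TNFRSF10B differed by -0.48 on the log2 scale. This list was outside under only 4 of 9 alternative settings, and its median was 0.10 with the mean over probe sets and 0.07 with the stricter level filter.

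Several lists of amino acid and protein metabolism were also higher. The 27 proteasome subunits above the filter had a median of 0.06 at percentile 99.95, with 20 higher. Their differences were small, from PSMD12 at -0.15 and PSMA2 at -0.08 to PSMD6 at 0.16 and PSMA4 at 0.26. The aminoacyl-tRNA synthetases, which charge tRNAs, had 9 of 15 higher and a median of 0.08 at percentile 99.4. WARS1 and VARS1 were 1.31- and 1.23-fold higher and FARSA and CARS1 1.16- and 1.15-fold lower. Both lists fell inside the central 95% against random lists not matched on signal, at percentiles 87.8 and 87.4. The synthetase list also fell inside with the mean or median over probe sets, at percentiles 93.2 and 94.5, with a median of 0.05. Targets of ATF4, the transcription factor of the amino acid response, had 12 of 21 genes higher and a median of 0.11 at percentile 99.2. The list lay inside with the median over probe sets, at percentile 96.4, and against random lists not matched on signal, at percentile 95.4. Asparagine synthetase (ASNS) was 1.78-fold and NUPR1 1.62-fold higher, while DDIT3 (CHOP) was 1.46-fold and ATF3 1.31-fold lower. Urea cycle and amino acid breakdown genes had 9 of 13 higher and a median of 0.17 at percentile 98.96, but lay inside with the list mean of 0.10, at percentile 94.2. HPD, of tyrosine breakdown, and NAGS, which makes the activator of the urea cycle, were 1.80- and 1.51-fold higher. The urea cycle enzymes ARG1 and CPS1 were 1.93- and 1.38-fold lower. The metallothionein list, with 5 of 7 genes higher, had a median of 0.18 at percentile 98.9. The metallothionein genes have near-identical relatives whose signals their probe sets may share. MT2A and MT1E were 1.38- and 1.25-fold higher. MT1X was 1.16-fold lower and the zinc exporter SLC30A1 1.70-fold lower, and the mean of the list was 0.04, at percentile 86.8. The list also lay inside against random lists not matched on signal, at percentile 94.7, and against lists also matched on gene span, at percentile 95.9, a setting chosen after the data were seen. With the housekeeping genes set equal, the medians were larger, at 0.15 for the proteasome, 0.17 for the synthetases, 0.19 for the ATF4 targets, 0.26 for the urea cycle list and 0.27 for the metallothioneins, and with the median over probe sets that of the proteasome was 0.03.

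Signalling lists downstream of receptor tyrosine kinases did not stand apart. The ERK output list had 8 of 14 genes higher and a median of 0.10 at percentile 93.2. IER3 was 1.63-fold and ETV1 1.38-fold higher, while the feedback inhibitor SPRY2 differed by -0.58 on the log2 scale and cyclin D1 (CCND1) was 1.44-fold lower. The median of the ERK output list was -0.01 with the stricter level filter, 0.02 without a level filter and 0.18 with the housekeeping genes set equal. FOXO targets, which AKT signalling restrains, had 7 of 13 genes lower and a median of -0.16 at percentile 9.30. That median was -0.05 with the mean or median over probe sets and -0.01 without a level filter, at percentile 53.5, while the stricter filter put the list at percentile 2.62. Among them the pro-apoptotic BCL2L11 (BIM) was 1.83-fold lower, TXNIP 1.46-fold lower, PINK1 1.69-fold higher and PIK3IP1 1.34-fold higher. Hepatocyte plasma proteins had 13 of 19 genes lower and a median of -0.09 at percentile 22.9, and 4 of the 19 were at least 1.5-fold lower. The list lay outside with 2 other settings, at percentile 0.13 with its mean of -0.24 and at percentile 1.90 with the median over probe sets, and its median was -0.01 without a level filter. HPX and APOC3, an apolipoprotein, were 2.56- and 1.87-fold lower, and the coagulation factors F2 and F7 each differed by 0.16.

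In all, 10 of 58 lists lay outside the central 95% of random lists, 8 of them higher and 2 lower, where about 2.9 would by construction. Genes of a list are often regulated together, so this excess is no test of an effect of the siRNA. Of the 12 cholangiocyte markers 8 passed the level filter. The 4 of 16 leukocyte markers that did had a median log2 difference of 0.36 and the 2 of 13 endothelial markers one of -0.20, too few for a percentile. Of the 13 fibroblast and stellate cell markers, the 5 that did had a median of -0.03 at percentile 24.2.

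**Figure D3:**
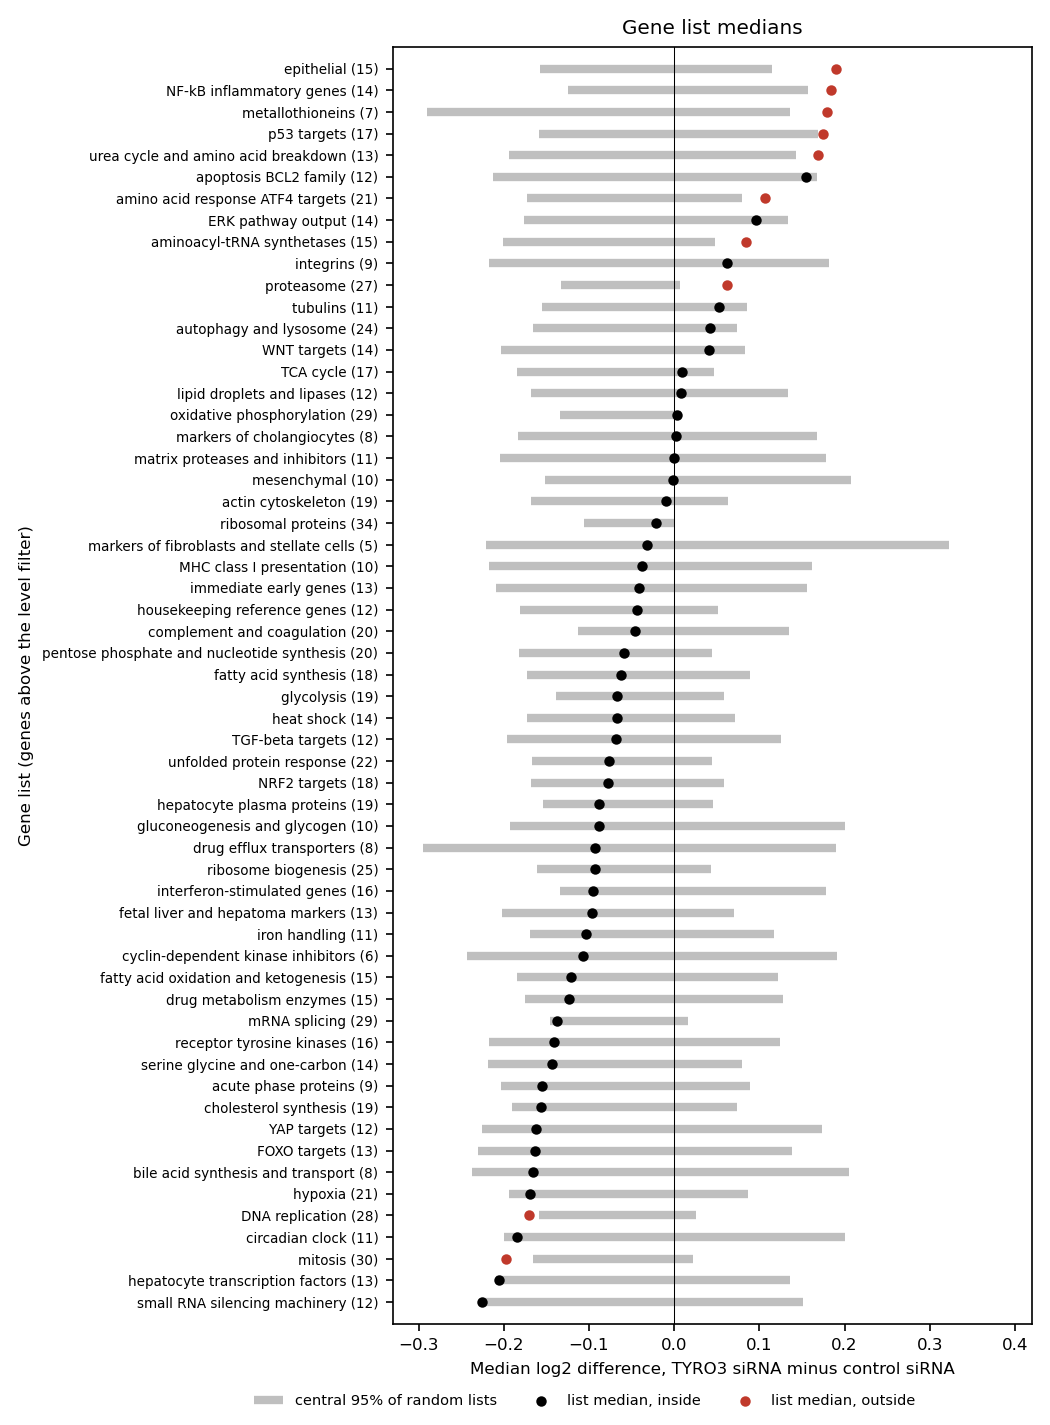
Median log2 difference, TYRO3 siRNA minus control siRNA (horizontal axis), of each gene list with at least 5 genes above the level filter (vertical axis, number of genes in parentheses). Grey bars are the central 95% of 10000 random lists matched on signal, and red points mark the 10 of 58 lists outside it, from mitosis at -0.20 to the epithelial list at 0.19.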

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

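Signals outside the gene values were looked at in probe sets that name no gene or several genes, since neither kind enters a gene value. Among 2307 probe sets above the level filter that name no gene in the annotation table, 4 were at least 2-fold higher and 7 at least 2-fold lower with TYRO3 siRNA. Their log2 differences ran from 1.03 to 1.22 for the higher and from -1.30 to -1.01 for the lower ones. Among 1010 probe sets above the filter that name several genes, 3 were at least 2-fold higher, by log2 differences of 1.56, 2.16 and 2.22, and 5 at least 2-fold lower, between -1.29 and -1.01. On the control array, 3 of the 4 higher probe sets that name no gene and 1 of the 3 that name several were under the level filter. A probe set that names several genes cannot by itself say which of its genes differs. The probe set at 2.16 names PTPMT1 and NDUFS3. Single-gene probe sets of PTPMT1 differed by 2.40 and 1.47 and the gene value of NDUFS3 by 0.09, so its difference goes with that of PTPMT1. The other probe sets are not named, and no explanation was tested for them.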

How the results depend on the processing

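TYRO3 was lower under all 4 alternatives run for it: -1.29 on the log2 scale with the mean or the median of its probe sets, where the deposited brighter probe set gave -1.80, and within the spread between probe sets of that value with the housekeeping genes set equal or the level trend removed. Counts of 52 higher and 67 lower genes became 30 and 26 with the mean of all probe sets, of which 25 and 24 were the same genes, and 32 and 35 with their median (24 and 26 the same). They became 308 and 460 at 1.5-fold, 6 and 5 at 3-fold, and 2 and 4 where every one of at least 2 probe sets had to pass. The other scalings and level filters stayed within 1.5 times. With the housekeeping genes set equal, 59.3% of the 2-fold genes were higher, against 43.7%. Of the 30 genes with the largest differences, 19 stayed past 2-fold with the mean and 18 with the median of their probe sets. With the median, PDCD6 turned to -0.26 and MAOB to -0.20, since their dimmer probe sets then decide the value. For 33 named genes other than TYRO3, 96 alternative values lay within 0.21 of the deposited one and 36 did not, and the small difference of MERTK also changed sign, to 0.04 and 0.05 with the mean and median of its probe sets. For 15 list medians, held against the spread of medians of matched random lists, 71 values stayed within it and 33 did not. Of these medians 7 values in 3 lists changed sign, those of interferon-stimulated genes, ERK output and mesenchymal genes, none of which stood apart in the values as deposited. Between 10 and 14 lists were outside the central 95% under the 9 alternatives, against 10, and 6 to 10 of them were the same lists. The alternative matched on gene span was chosen after the data were seen. The mitosis, epithelial and NF-kB lists were outside under all 9, DNA replication, the proteasome and the urea cycle list under 8, the ATF4 list under 7, metallothioneins and tRNA synthetases under 6 and p53 targets under 4. Scaling to housekeeping genes shifts all values by a constant, so it can hardly move a percentile. Removal of the level trend is also a weak check of a list, since the random lists were already matched on level. Both settings count among the 9, and among the 4 of the p53 targets. The spread between probe sets of one gene was 0.24 without a level filter and 0.18 at the 60th percentile, so probe sets of one gene disagreed more where dim ones were included. No replicate could be left out, and no setting stands in for the missing spread between cultures.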

Other observations

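A scan of all 165 gene families that share a symbol root and have at least 8 genes above the filter, run after the data were seen, gave 12 outside the central 95% of random lists matched on signal and gene span, where about 8.25 would be by construction. The scan, its minimum size and the roots it left out were set up after high S100 values had been noticed while looking through families picked by hand, so the S100A family was chosen after its values were seen. The S100A calcium-binding proteins were among the highest, with 10 of 11 genes higher, a median log2 difference of 0.40 and percentile 99.96, and a median of 0.49 with the housekeeping genes set equal or with the level trend removed. S100A6 and S100A14 differed by 0.84 and 0.83, S100A11 by 0.70 and S100A4 by 0.62. The related S100P, outside that root, differed by 1.13. At the other end, 197 of 315 zinc finger genes with ZNF symbols were lower, with a small median of -0.07 that lay below all 10000 random lists (percentile 0). That direction depends on the scaling chosen. With the housekeeping genes set equal 172 were higher and 143 lower, with a median of 0.02. With the level trend removed 118 were higher and 197 lower, with a median of -0.06. The place of the family among random lists does not move with a constant shift such as the housekeeping scaling. The highest and lowest of them differed by 0.96 and -0.93.

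Apart from the removal of the level trend, which was planned, the tests that follow were chosen after the results they address had been seen. The trend with gene span, the medians by level and the medians by chromosome had also been looked at before the span, level and neighbour tests were run. The first pattern is the 10 lists that stand apart. Log2 differences were slightly lower in genes of larger genomic span (Spearman rho -0.17 across 11857 genes, which are not independent), with a median of 0.08 in bin 1 of 10, the shortest genes, -0.08 in bins 8 and 9, and -0.03 in bin 10, the longest. A gene span trend as the whole cause is argued against, since 10 lists stayed outside with random lists matched on level and gene span, 9 of them the same; the metallothioneins left, at percentile 95.9. Removing the level trend left 13 lists outside, which decides nothing about a shift shared with the level of expression, because the random lists were already matched on level. Against random lists not matched on level, 6 of the 10 stayed outside. A difference between the 2 cultures other than TYRO3, such as density or transfection, stays open, as does joint regulation of the genes of a list, and neither can be addressed with 1 array per group.

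The second pattern is the higher MET signal. A fault of one probe set is argued against, as 3 of the 3 other MET probe sets were higher by more than the spread of 0.21, 2 of them above the level filter, by 1.39 and 1.46, and 1 below it. The rule for naming genes had already required the probe sets above the filter to agree in sign, though not in size. A gain of a chromosome region wide enough to hold the 20 nearest measured genes is argued against by their values. Their median log2 difference was -0.25, with 5 of 20 higher and a lowest value of -1.41, that of FAM3C. A narrower gain of MET alone or with a few neighbours is not addressed, since it would hardly move a median over 20 genes. Knockdown of TYRO3, an off-target effect of the siRNA and a difference between the cultures all stay open, as no other siRNA, rescue or replicate culture was analysed here.

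The third pattern is the lower NDUFB7 signal, with a log2 difference of -2.44 on its brighter probe set and -1.34 as the mean of both. A fall of complex I genes together is argued against by the other 32 measured NDUF subunits, whose median log2 difference was -0.019 with a range from -0.97 to 0.30. A fault of one probe set cannot be told apart from a change of the transcript. The other NDUFB7 probe set differed by -0.25 but lies below the level filter.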
